A study of Homo sapiens with 12 samples.

How the data were processed

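MicroRNA levels were measured by reverse transcription and quantitative PCR in MCF-10A cells, an immortalised, non-tumorigenic human breast epithelial line, that carried a doxycycline-inducible construct. Cells were left untreated or were given 2 µg/ml doxycycline for 48 hours, with 3 biological replicates per condition, and each of the 6 RNA samples was run on 2 TaqMan low-density array cards, called A and B. This gives 12 arrays. Per the labels' protocols, 60 ng of total RNA was reverse transcribed with miRNA-specific stem-loop primers, pre-amplified for 12 cycles and amplified with FAM-labelled TaqMan probes. Pre-amplification comes before quantification, so assays that amplify unevenly at that step carry the difference into their threshold cycle.

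The raw tables hold threshold cycles (Ct), the PCR cycle at which fluorescence crosses a set level, or the word Undetermined, as deposited by the authors without normalization. A Ct lower by 1 cycle stands for about 2 times as much template. The instrument software, baseline and threshold settings are not given in the sources used here. The second pair of tables holds ratios, fold changes of each sample over untreated replicate A, which per the file headers are 2 raised to minus the difference in delta Ct, with delta Ct taken against housekeeping genes. These ratios cover the assays with a Ct in all 6 samples, 200 on card A and 122 on card B. The raw Ct values and the deposited ratios together showed which reference the authors had used. From them the reference difference of each sample from untreated replicate A was worked out, averaged over the assays of the card. On each card exactly 1 pair of assays had a mean Ct that matched this difference in every sample within 0.001 on the log2 scale. Those 2 assays are called the authors' reference assays below.

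Both kinds of table identify an assay only by a number, and nothing in the files pairs these numbers with miRNA names. No name was assigned from a number. The 24 lists of miRNA families, pathway-linked miRNAs and cell type markers fixed before the data were examined were therefore not tested, the same holds for the planned normalizations to U6 and to RNU44 with RNU48, and other control assays could not be set aside. Which card a table belongs to was taken from the name of the table, since the sample labels used as its column heads are shared by both cards.

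Each card was analysed separately. The authors' 2 reference assays were removed, leaving 369 assays on card A and 377 on card B. A Ct under 35 counted as detected, and any other value was set to Ct 35. From every Ct the mean Ct of the assays detected in all 6 samples of that card was subtracted (194 assays on card A, 112 on card B), and the sign was turned so that a higher value means more miRNA. These values are log2 levels relative to the card mean. Assays detected in at least 3 of the 6 samples were tested, 211 on card A and 139 on card B. Of the values tested, 35 of 1266 on card A and 56 of 834 on card B had been set to Ct 35. The changes of assays with such values are less certain. They tend to be understated where only values of the condition with the lower level were set. Where only values of the condition with the higher level were set, they tend to be overstated. Doxycycline was compared with untreated by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 3 samples against 3, without a block, two-sided, with Benjamini-Hochberg adjustment within the card and a threshold of adjusted p = 0.05. Intervals are 95% confidence intervals from this model, for each assay alone and not adjusted for the number of assays tested. For assays picked by a small p, the differences and intervals tend to lie too far from no change. Card-wide values and the authors' reference assays were compared by exact two-sided permutation tests, in which 3 against 3 cannot give a p below 0.1. The labels call the replicates biological triplicates, without saying whether they came from separate cultures set up on different days.

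The rule for the assays described, fixed beforehand, took on each card the assays past the threshold and filled up with the smallest unadjusted p to 20 on card A and 10 on card B. Because the numbers carry no names, they are printed for card A assays 377, 56 and 62 only, and the others are described by their values. Alternatives were other references (median of the detected assays, quantile normalization, no normalization), detection limits of Ct 32 and Ct 38, a filter on detection in all 6 samples, no filter, the replicate letter as a block, a variance trend with robust estimation (statmod 1.5.0), an unequal-variance test per assay, adjustment over both cards together and leaving out each sample. The authors' reference assays as reference and a threshold of 0.1 were added after seeing the data. So were a block on the number of assays detected and a count of changes over 2-fold among assays with a mean Ct under 28.

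The procedure was tested on simulated data, with 20 assays changed in each of 20 simulated data sets per card, drawn from the measured means and within-group spreads. For card A and its 211 assays, 90.2% of the 2-fold changes were called among assays with a mean Ct under 28, and 22.4% among dimmer ones. For card B and its 139 assays these shares were 75.4% and 29.9%. Unchanged assays made up 3.26% of the calls on card A and 6.69% on card B.

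Precision is limited by the number of arrays and by the Ct of an assay. On card A the median SD within a condition was 0.14 on the log2 scale for the 66 assays with a mean Ct of 20 to 25 and 0.93 for the 28 assays with a mean Ct from 32 to 35. On card B the corresponding medians were 0.13 (15 assays) and 1.00 (37 assays).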

Results

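The series asked which miRNAs change in MCF-10A breast epithelial cells when STAT3, a transcription factor activated by cytokines such as IL-6, is specifically activated. Treated cells had received doxycycline, which switches on an inducible construct, and untreated cells served as controls. STAT3 activation is named by the title of the series, while the sample labels do not say what the construct holds, and neither STAT3 nor its activity was measured in the data used here. All 6 samples were of the inducible cells, so the comparison holds the effect of the induced construct together with any effect of the drug itself. Levels were read on card A, with 371 assays, and card B, with 379 assays. Assays are known here by number only, so no miRNA is named.

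The cells had a Ct under 35 for a larger part of card A than of card B. On card A between 208 and 213 assays were detected per sample, and on card B between 128 and 148. Detection on card A was 208.7 ± 1.15 assays (SD, n = 3) in untreated and 211.7 ± 1.15 (SD, n = 3) in doxycycline-treated cells, with no overlap between the conditions (exact permutation p = 0.1, the smallest possible). On card B it was 140.7 ± 8.74 and 134.7 ± 9.07 (SD, n = 3 each, exact permutation p = 0.5). No Ct was recorded in any sample for 115 assays of card A and 178 of card B. No assay on either card was detected in all 3 samples of one condition and in none of the other.

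Mean Ct and the authors' reference assays differed between the conditions by no more than the samples differed among themselves. The mean Ct of the card A assays detected in all samples was 25.6 ± 0.219 (SD, n = 3) in untreated and 25.4 ± 0.202 (SD, n = 3) in treated cells (exact permutation p = 0.5). On card B it was 28.04 ± 0.134 and 28.14 ± 0.234 (SD, n = 3 each, exact permutation p = 0.6). The mean Ct of the 2 reference assays differed by -0.02 cycles, treated minus untreated, on card A (exact permutation p = 1) and by 0.08 cycles on card B (exact permutation p = 0.8, n = 3 per condition). The 2 reference assays of card A did not move together in replicate C of either condition. The first had a Ct of 16.4 in treated replicate C, against 17.2 and 17.6 in the other treated replicates, and of 16.8 in untreated replicate C, against 17.1 and 17.4. The second had 15.6, against 15.4 and 15.7, in both conditions.

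On card A, 2 of the 211 tested assays rose after doxycycline and none fell past the threshold. Assay 377 rose 7.93-fold, the largest fitted change among the tested assays of the card, where undetected values stand at Ct 35. Assay 56, which had a lower Ct, rose 3.44-fold. The level of assay 377 went from -4.05 ± 0.27 to -1.06 ± 0.12 on the log2 scale relative to the card mean (SD, n = 3 each), a difference of 2.99 with a standard error of 0.17 and a 95% interval of 2.55 to 3.42 (limma, adjusted p = 0.000955). The raw Ct of this assay was 29.6 ± 0.291 in untreated and 26.5 ± 0.302 in treated cells. Assay 56 went from 0.97 ± 0.14 to 2.75 ± 0.12 (SD, n = 3 each), a difference of 1.78 with a standard error of 0.13 and a 95% interval of 1.45 to 2.12 (limma, adjusted p = 0.0019). Its raw Ct was 24.6 ± 0.263 in untreated and 22.7 ± 0.322 in treated cells. In the authors' deposited table, assay 377 stood at 10.1, 8.88 and 9.55 times untreated replicate A in the treated replicates A, B and C, and at 1.04 and 1.23 times in untreated replicates B and C. In the authors' deposited table, assay 56 stood at 3.27, 3.15 and 3.21 times in the treated and at 0.855 and 0.707 times in the untreated replicates. Averaged over the replicates of that table, these were the 2 highest increases among its card A assays. That table rests on the same Ct values with another reference per sample, so this order gives no separate support. Among the tested assays, one detected in 1 untreated and 2 treated samples had a larger fitted increase than assay 56. Its difference was 2.11 on the log2 scale (limma, adjusted p = 0.459). With the replicate letter as a block assay 56 fell short of the threshold (limma, adjusted p = 0.0755), and with an unequal-variance test per assay 377 did (adjusted p = 0.0665). Without treated replicate B, or with 4 of the other settings, 1 assay was called lower, and without treated replicate A 1 further assay was called higher.

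**Figure D1:**
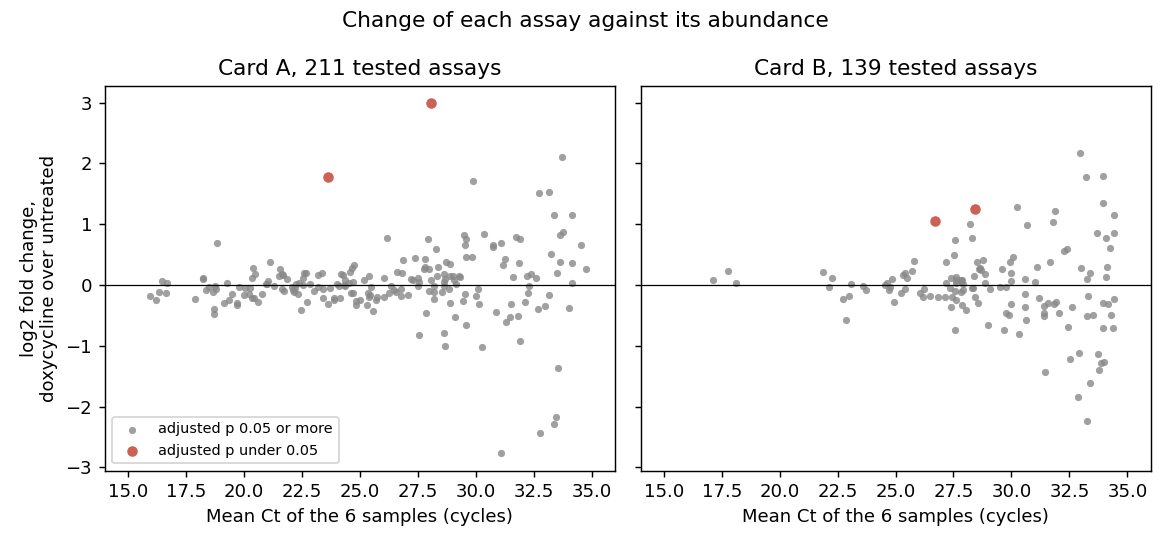
The log2 fold change of doxycycline-treated over untreated cells (vertical axis) is plotted against the mean Ct over the 6 samples (horizontal axis, in cycles). Every tested assay is shown, 211 on card A and 139 on card B. For the same assay, a higher Ct means less miRNA. Red points are the 2 assays per card with an adjusted p under 0.05, all above 0, and grey points scatter more widely where the mean Ct is 30 or more.

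Most other card A assays with a mean Ct under 28 stayed close to their untreated level. Among the 127 tested assays with a mean Ct under 28, 122 (96.1%) differed by less than 0.5 on the log2 scale, and assay 56 was the only one that differed by over 2-fold. That count was 2 without untreated replicate A, treated replicate A or treated replicate C. The remaining ones lay between -0.83 and 0.78. Across the assays detected in all samples, the mean levels of both conditions correlated with r = 0.993, a correlation across assays, which are not independent replicates. Levels differed far more between assays than between conditions, so r would be high even with many changed assays and does not measure their changes.

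Of the 20 card A assays chosen by the rule, 18 did not pass the threshold, with adjusted p between 0.0608 and 0.387 in limma. Of these, 8 had higher values after doxycycline, by 0.34 to 1.51 on the log2 scale, and 10 had lower values, by -2.77 to -0.32. The lowest adjusted p among them was that of assay 62, at -4.19 ± 0.66 in untreated and -6.96 ± 0.56 in treated cells (SD, n = 3 each). This difference, 6.81-fold lower, had a 95% interval of -3.84 to -1.70 on the log2 scale (limma, adjusted p = 0.0608). Its raw Ct was 29.8 ± 0.873 and 32.4 ± 0.554. At an unadjusted p under 0.05 there were 25 assays, 13 higher and 12 lower, where 10.6 would be expected by chance. The 2 conditions did not overlap for 34 assays (16.1%), where chance gives 10%. Assays of the same samples are not independent, so a single grouping can lie far from these averages. Other groupings of the samples were not counted in this way, so neither count shows an excess over chance.

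On card B, 2 of the 139 tested assays rose and none fell past the threshold. The larger increase was 2.37-fold and the smaller 2.08-fold. The level of the first went from -0.95 ± 0.12 to 0.30 ± 0.15 on the log2 scale (SD, n = 3 each), a difference of 1.24 with a 95% interval of 0.86 to 1.62 (limma, adjusted p = 0.0347). The second went from 0.88 ± 0.08 to 1.94 ± 0.15 (SD, n = 3 each), a difference of 1.06 with a 95% interval of 0.70 to 1.42 (limma, adjusted p = 0.0347). Their raw Ct was 29.0 ± 0.239 and 27.2 ± 0.101 in untreated cells and 27.8 ± 0.378 and 26.2 ± 0.275 in treated cells. In the authors' deposited table the first stood at 2.03, 2.47 and 2.13 times untreated replicate A in the treated replicates, and the second at 2.26, 2.15 and 2.11 times. In untreated replicates B and C of the authors' deposited table the first stood at 1.04 and 0.797 times and the second at 1.22 and 0.957 times. Averaged over the replicates of that table, they ranked 4 and 6 among the increases of its card B assays. Both card B calls fell short of the threshold when the authors' reference assays served as reference (limma, adjusted p = 0.0832 for each), with the median reference, no normalization, the replicate block or an unequal-variance test, and also without any one of the 6 samples, while their differences stayed between 0.98 and 1.32 with a sample left out. The number of assays detected separated untreated replicates A and C and treated replicate B (143 to 148) from the other 3 samples (128 to 131), and the difference of the first assay was 1.41 within the former and 1.15 within the latter, that of the second 1.08 and 0.99, while with this split as a block the adjusted p were 0.0758 and 0.0917 (limma).

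**Figure D2:**
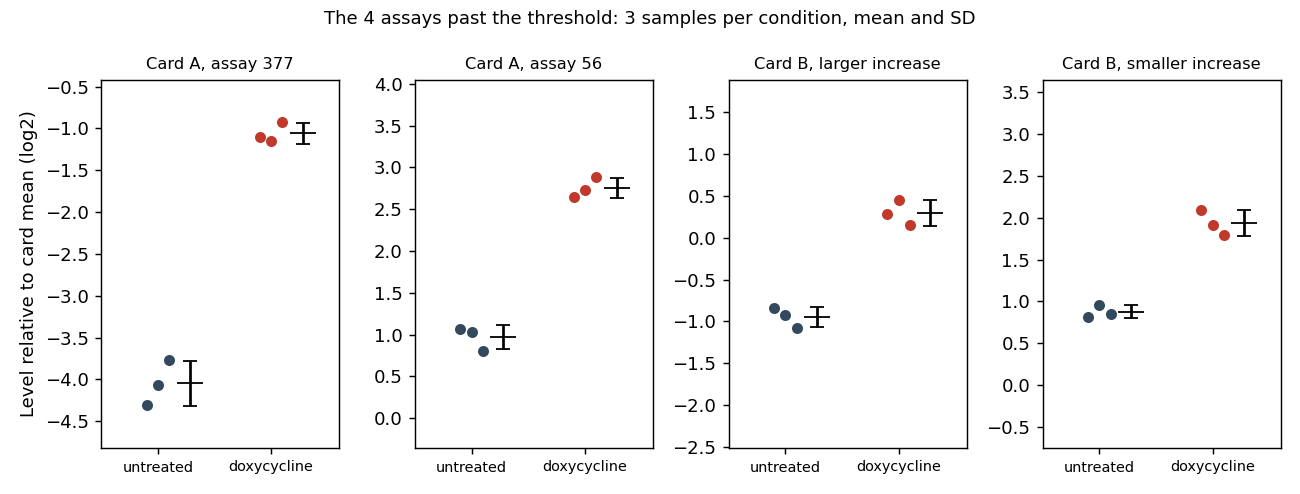
Level relative to the card mean on the log2 scale (vertical axis, the same span in each panel) is shown for the 4 assays past the threshold, with 1 point per sample (3 untreated, 3 doxycycline-treated) and the mean ± SD beside them. The treated points lie above all untreated points in every panel, from -4.05 to -1.06 on average for card A assay 377 and from 0.88 to 1.94 for the smaller increase on card B.

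Among the 53 tested assays of card B with a mean Ct under 28, 49 (92.5%) differed by less than 0.5 on the log2 scale, and the assay with the smaller of the 2 called increases was the only one over 2-fold. That count was 0 with the median reference, without normalization or without treated replicate A, and 2 without treated replicate C. Of the 10 card B assays chosen by the rule, 8 did not pass the threshold (limma, adjusted p from 0.154 to 0.440). Of these, 2 had higher values, by 0.73 and 0.78 on the log2 scale, and 6 had lower values, by -2.24 to -0.42. At an unadjusted p under 0.05 there were 10 assays, 4 higher and 6 lower, where 6.95 would be expected by chance. The conditions did not overlap for 24 assays (17.3%), where chance gives 10%. As on card A, a single grouping can lie far from these averages, so neither count shows an excess over chance.

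Most differences over 2-fold were seen among assays with a mean Ct of 30 or more, and none of those passed the threshold. On card A, 11 of the 49 tested assays with a mean Ct of 30 or more differed by over 2-fold, 5 higher and 6 lower, against 3 of the 35 with a mean Ct from 28 to 30. On card B these were 18 of 58, 8 higher and 10 lower, against 2 of 28. A 2-fold change was mostly not detectable among assays with a mean Ct of 28 or more. In the simulations, 22.4% of such changes on card A and 29.9% on card B were called. Assays with a mean Ct of 30 or more were not simulated apart from these. The median SD within a condition was 0.42 on card A and 0.29 on card B at a mean Ct of 28 to 30. It was 0.77 and 0.68 at 30 to 32. Simulated changes of 2 on the log2 scale were called in 56.5% and 54.2% of cases at a mean Ct of 28 or more, and changes of 3 in 78.1% and 78.6%. Each simulated data set held more changed assays than passed the threshold on either card, which eases the Benjamini-Hochberg adjustment. The simulated spreads were also measured after undetected values had been set to Ct 35, which can understate the spread of assays with a high Ct. The shares called can therefore be too high for the measured data, and for assays with a mean Ct of 30 or more.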

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

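The ratio over references (the references themselves were planned, except the authors' 2 assays) and the test of the detection limit were chosen after the result was seen, and the tests of other splits and of single samples before.

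Outside the tested assays, 24 of card A and 36 of card B were detected in only 1 or 2 samples. A few of these were detected in 2 samples of the same condition, without a common direction over the 2 cards. On card A, 3 assays had a Ct under 35 in 2 treated samples and in no untreated sample, and 0 showed the reverse. On card B, 2 assays did so and 4 showed the reverse, 3 of those 4 in the untreated replicates A and C, which had more assays detected than untreated replicate B. These assays were not tested, since too few samples gave a Ct.

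The pattern weighed is the increase of 4 assays, 2 on each card. A change of the reference as its whole source is argued against: over 4 other references the lowest ratio of a log2 fold change to its reported value was 0.909, although 3 of these references ended both card B calls (limma, adjusted p from 0.0561 to 0.223). For error near the detection limit, the highest untreated mean Ct among the 4 was 29.6, under the cut of Ct 32 set for this test. The spread within a condition was larger at a high Ct, so picking assays by a small p favours a low Ct. Their Ct therefore does not exclude such error. No single sample carried the increases, since with each sample left out the log2 fold changes were at least 0.923 of their reported values. Both card B calls were lost in each of these 6 fits (limma, adjusted p from 0.0508 to 0.189). The 4 assays had been picked for a small p in these same samples, which favours a high ratio, so it adds no separate support. Other splits of the samples are too few to give a share under 0.05: of 10 splits on card A, 2 gave 2 or more assays past the threshold, the real one included (real value 2, highest other 3), and of 10 on card B, 1 did, the real one (real value 2, highest other 1). An effect of doxycycline itself, apart from the induced construct, stays open and was not tested, as does the biological difference the design names.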

How the results depend on the processing

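On card A, 2 assays passed the threshold in the analysis reported, and both did under every reference, filter, detection limit and adjustment tried and with any sample left out, with 2.87 to 3.15 on the log2 scale for assay 377 and 1.70 to 1.95 for assay 56. The exceptions were the replicate block and the unequal-variance test per assay, with 1 assay each. The replicate block, which takes residual degrees of freedom from the fit, ended the call of assay 56 (adjusted p = 0.0755 in limma, range over its alternatives 2.62e-07 to 0.0755), and the unequal-variance test that of assay 377 (adjusted p = 0.0665, range over its alternatives 4.21e-07 to 0.0665). Assay 62, with lower values after doxycycline, passed the threshold with detection required in all 6 samples, with a limit of Ct 32, with a variance trend and robust estimation, and at a threshold of 0.1 (3 assays each). Without treated replicate A 1 further assay rose past the threshold, and without treated replicate B 1 other assay fell past it, which makes 3 assays in each case. On card B, 2 assays passed, and 0 did with the median or the authors' 2 assays as reference, without normalization, with the replicate block, with the block by the number of assays detected and with the unequal-variance test per assay, while the trend with robust estimation gave 3, all higher. The count without each sample in turn was 0 to 0, and each of the 6 samples ended both calls. The direction never reversed, and the log2 fold changes of both assays stayed between 0.96 and 1.32 over all alternatives, with adjusted p up to 0.299. Fewer samples lower the degrees of freedom; otherwise the cause was not tested. The deviations of same-lettered samples correlated little over the assays (-0.09, 0.17 and -0.14 on card A and -0.03, -0.08 and -0.10 on card B). This does not exclude a pairing by letter. The first reference assay of card A had its lowest Ct in replicate C of both conditions, 16.8 in untreated and 16.4 in treated cells. The letters are not said to pair cultures across the conditions, so they were not taken as pairs. A median reference moved the median change of all assays from -0.01 to 0.15 on card A and from -0.03 to -0.12 on card B, and no normalization moved it to 0.15 and -0.13, and the authors' assays to 0.13 and -0.04. Normalization to U6 and to RNU44 with RNU48, and the tests of miRNA lists, were not run because the assay numbers carry no names.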

Other observations

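Tests here were fixed before their result was seen. The largest decreases after doxycycline belonged to assays with a high mean Ct, which raised the hypothesis of a loss of rare miRNAs on card A. Among its 49 assays with a mean Ct of 30 or more, 6 were lower and 5 higher by over 1 on the log2 scale. All 10 splits of the 6 samples into 3 and 3, the real one included, had at least 6 that far to one side. Another split had up to 10. Only lower values were counted in the real split and the side with more in the others, which favours this outcome. The splits therefore do not decide between the error of dim assays and a loss. The counts of 6 lower and 5 higher show little excess of lower values. The mean number of assays detected on card A did not fall either, at 208.7 in untreated and 211.7 in treated cells. Those numbers were not corrected for the mean Ct of the samples.

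The same RNA ran on both cards, and treated replicate C had the lowest mean Ct of the 6 samples on card A, 25.2, and the highest on card B, 28.3. The mean over the assays detected in all samples was 25.8 on card A and 28.1 on card B for untreated replicate B.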
